A study of Mus musculus with 5 samples.

How the data were processed

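RNA sequencing was carried out on 5 mouse libraries, 1 each from blood cells (PB), bone marrow (BM), the myeloid-like cell complex (MCC), mouse embryonic fibroblasts (MEF) and induced pluripotent stem cells (iPSC). Per the labels' protocols, polyA RNA was taken from total RNA extracted with Trizol. The values are deposited as whole-number read counts per gene symbol for each library, not normalized; per the submitters' processing notes, STAR, featureCounts and the mm10 build were used. Tool versions, the gene annotation, the strand setting and any filter are not given in the sources used here. The table held 34970 gene symbols and 5 columns, each matched to its library by name, and 0 columns were left unused. Total counts ranged from 30078366 to 47557598, and between 24445 and 28197 genes had at least 1 read. Haemoglobin genes took 9.04% of the counts in PB, 1.06% in BM, 0.00102% in MCC and 0% in MEF. Mitochondrial genes took 1.33% in PB, 0.940% in BM, 2.28% in MCC, 1.35% in MEF and 1.80% in iPSC, and ribosomal protein genes 5.22%, 5.00%, 12.4%, 10.1% and 9.20%. The 10 most abundant genes took 11.9% of the counts in PB, 8.45% in BM, 7.28% in MCC, 6.15% in MEF and 5.78% in iPSC.

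From the deposited counts, CPM values were computed on library sizes scaled by the trimmed mean of M values (TMM) over all 5 libraries, with edgeR 4.0.16 in R 4.3.3. The remaining steps were done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the plots with matplotlib 3.10.9. MCC was compared with each of the other 4 libraries. With 1 library per group there was no spread between replicates to test against, so genes were counted by a rule of size, a CPM ratio of at least 4-fold, with counts under 3 set to 3, and at least 5 CPM in the higher library. Each ratio carries an exact 95% interval (Clopper-Pearson, conditional binomial), which covers counting error only and says nothing of the spread between animals or cultures. Sequenced reads carried no stated molecular identifiers and are not independent molecules. Where a library had 0 reads of a gene, the ratio was taken against a floor of 3 counts and is given as a lower bound; the floor was 0.100 CPM in PB, 0.0736 in BM, 0.0694 in MCC, 0.0694 in MEF and 0.0574 in iPSC. Ratios with 1 to 3 reads on one side are given with their interval.

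Gene groups were 42 lists of cell type and pathway genes, fixed before the data were examined, with 869 entries and 797 distinct genes, of which 791 were in the table. The remaining symbols were not analysed here. Members with at least 1 CPM in at least 1 library were counted as measured. The median log2 ratio of a list was placed among those of 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. Some genes are on several lists; 22 of the macrophage and monocyte members are also on another list, and 39 of them reached 5 CPM in BM. Correlations were taken over the 18416 genes at 1 CPM or more in at least 1 library. For the position of MCC, genes at least 8-fold apart between a native library and MEF were counted, beside 100 simulated unchanged libraries drawn from MEF.

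The genes to be named were set by a rule fixed before the data were examined. For each comparison the rule took the 8 genes in each direction with the largest counting bound, leaving out predicted genes and clones, mitochondrial genes, immunoglobulin and T cell receptor segments and haemoglobins. It added, from each list described, the 2 members highest in MCC and the 2 highest in the other library, and the genes of the reprogramming factor, pluripotency and sex-linked lists. Other genes named were chosen after their values were seen and are said to be so. Some genes that the rule takes are not reported here.

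The calculation was tested on simulated data for each of the 4 comparisons, with 34970 genes. Of these, 100 were made 8-fold higher and 100 made 8-fold lower, all drawn from genes well above the 5 CPM minimum. The draws held counting error only, and the true scaling was supplied. The outcome thus checks the arithmetic of the rule, not the spread between cultures or the choice of scaling. All 100 were recovered in each direction in each comparison, 0 unchanged genes were called, and 96.5% of the intervals held the true ratio for MEF, 96.5% for BM, 96.7% for PB and 96.5% for iPSC. The alternatives tried were DESeq2 1.42.0 size factors, total counts without further scaling, no filter on the level, a minimum of 20 CPM, the counting bound in place of the ratio, and the removal of the 10 most abundant genes of each library with mitochondrial genes and haemoglobins. For correlations they were Pearson's coefficient, a minimum of 5 CPM and the 2000 most variable genes, for lists the mean, all members and members on no other list, and for the position 16-fold and PB as reference.

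Gene positions came from GENCODE release M21 on mm10, in which 33820 symbols were matched, 33782 of them once. Because the strand setting is not given in the sources used here, reads of a gene and of an overlapping gene on the opposite strand are not separated: the exonic bases so shared were 23.2% for Ccn2, 20.7% for Cebpb, 63.1% for Folr2 and 23.1% for Mest. Counts are also uncertain for genes with near-identical copies, among those named Lyz2 (with Lyz1), Krt6a (with Krt6b), the haemoglobin genes, the actin genes Acta1 and Acta2, Gimap3 and Gimap6, and Eif2s3y. The library code of PB lies far from the other 4, and with 1 PB library no value within a batch could be had.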

Results

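RNA sequencing profiles were compared for 5 kinds of mouse cells, with 1 library each. MEF is the library of mouse embryonic fibroblasts, connective tissue cells of the embryo. MCC is the library labelled as a myeloid-like cell complex, in a series whose title concerns turning fibroblasts directly into macrophages. BM is the library of bone marrow, and PB that of blood cells, which the design text describes as CD45-positive, CD45 being the surface protein of leukocytes encoded by Ptprc. The iPSC library came from induced pluripotent stem cells. How the MCC cells were made, and from which fibroblasts, is not given in the sources used here. Total counts were 30078366 in PB, 40774101 in BM, 47557598 in MCC, 46517281 in MEF and 43800105 in iPSC. With 1 library per group, no difference below has a replicate check and no p-value is given: values compare these libraries. The folds are followed by 95% counting intervals, which cover counting error only. Levels are given as CPM, counts scaled to a common library size. The PB library carries a library code far from those of the other 4 libraries, so a batch and the PB group cannot be told apart.

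Genes that mark each cell type were first read in every library as a check of the labels. Of 25 pluripotency genes, 25 were at 5 CPM or more in iPSC, against 2 in MCC and 2 in MEF. Pou5f1, which encodes the pluripotency factor OCT4, stood at 325 CPM in iPSC, 0.347 in MCC and 0.0925 in MEF, and Nanog at 241, 0.486 and 0.740 CPM. Of 37 fibroblast and matrix genes, 37 reached 5 CPM in MEF, 36 in MCC, 27 in iPSC, 14 in BM and 5 in PB. Neutrophil granule genes had a median of 1103 CPM in BM and 74.1 CPM in PB, and T and NK cell genes 7.79 and 102 CPM. Haemoglobin transcripts took 9.04% of the PB counts, 1.06% of the BM counts and 0.00102% of the MCC counts. Xist, the RNA of the inactive X chromosome, was at 99.8 CPM in MCC, 57.7 in MEF, 295 in PB, 35.3 in iPSC and 0.0245 in BM. The Y-linked gene Ddx3y was at 19 CPM in MCC, 44.3 in MEF, 124 in PB, 26.6 in BM and 0.0765 in iPSC. Eif2s3y, Kdm5d and Uty, also Y-linked, were each at 0.0191 CPM in iPSC, or 1 read, and between 13.9 and 73.8 CPM in the other 4 libraries. Xist and Y-linked transcripts were thus both present in MCC, MEF and PB. BM held Y-linked transcripts with Xist at a trace, and iPSC held Xist with Y-linked ones at a trace. Xist was higher and Ddx3y lower in MCC than in MEF. The sex of the cells therefore cannot be told apart from the groups.

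The comparison of MCC with MEF set the MCC cells against fibroblasts, the starting cell type named in the series title. Most macrophage genes were at high levels in MCC and near 0 in MEF. C1qb, a subunit of the complement protein C1q made largely by macrophages, stood at 2288 CPM in MCC and 0.162 CPM in MEF, 14136-fold (6861 to 35162) higher. Adgre1, a surface receptor used as a macrophage marker, had 400.1 CPM in MCC and 0 reads in MEF, at least 5768-fold higher. Of 42 macrophage and monocyte genes, 35 were at least 4-fold higher in MCC at 5 CPM or more and 0 were lower, with a median log2 ratio of 9.86. That median was at the 100th percentile of 10000 random lists matched on expression. Lyz2, the lysozyme of myeloid cells, was 3559.7-fold (2808 to 4584) higher. The mannose receptor gene Mrc1 was 7459-fold (2913 to 27379) higher. C1qa, C1qc and the Fc receptor genes Fcrls and Fcgr2b completed the group with the largest counting bounds, at 972, 1615, 682 and 657 CPM in MCC, and none was above 0.139 CPM in MEF. The C1q genes lie together on mm10 chromosome 4, 136880129 to 136886187 for C1qb, 136889804 to 136893065 for C1qc and 136895917 to 136898803 for C1qa. Adgre1 lies on chromosome 17, 57358691 to 57483527. Spp1 (osteopontin) was high in both libraries, at 5496 CPM in MCC and 1956 CPM in MEF, a ratio of 2.81-fold (2.79 to 2.83). Of the 7 macrophage and monocyte genes short of the threshold, 5 stayed below 5 CPM in MCC, chosen here after their values were seen. They were the monocyte genes Ly6c2, Ccr2 and Cx3cr1 at 0.185, 0.717 and 0.555 CPM, the lectin gene Clec7a at 1.13 CPM and the haemoglobin scavenger receptor gene Cd163 at 0.995 CPM.

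**Figure D1:**
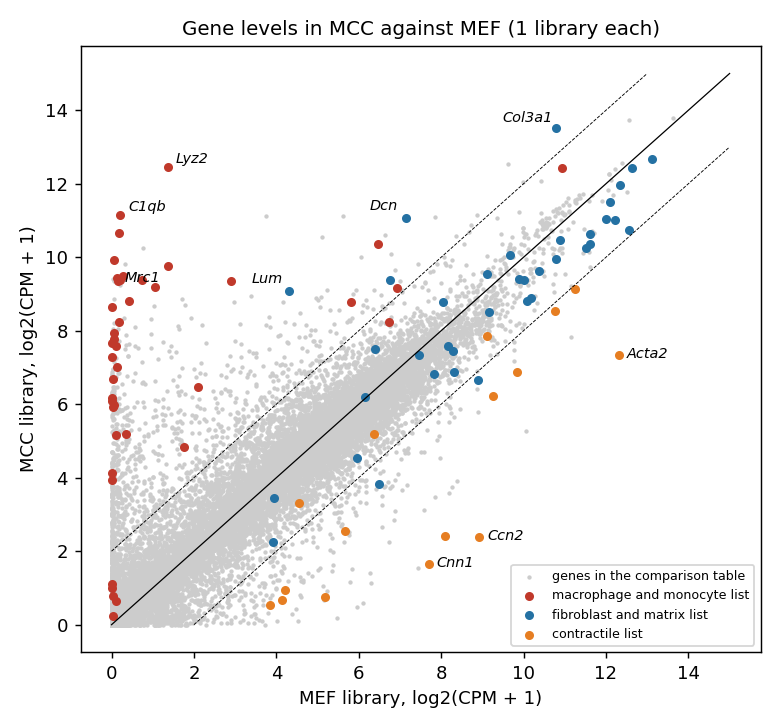
Each point is a gene at 1 CPM or more in any library, with its log2(CPM + 1) in the MEF library on the x axis and in the MCC library on the y axis; the solid line marks equal levels and the dashed lines a 4-fold difference in CPM + 1. Most macrophage and monocyte genes (red) lie along the left edge, 35 of 42 at least 4-fold higher in MCC, 31 of 37 fibroblast and matrix genes (blue) did not pass 4-fold, with 4 higher and 2 lower, and most contractile genes (orange) lie below it, 13 of 16 at least 4-fold lower.

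Most pan-leukocyte genes were also higher in MCC than in MEF, and other immune groups differed by gene. Of 20 pan-leukocyte genes, 15 were at least 4-fold higher and 0 lower (median log2 ratio 8.88). Ptprc, which encodes CD45 and is named, after its values were seen, because the design text gives CD45, was at 64.3 CPM in MCC and 0.0694 CPM in MEF. Laptm5, a lysosomal membrane protein of blood cells, was 995-fold (693 to 1487) higher, and Lcp1, a leukocyte actin-bundling protein, 393-fold (294 to 539) higher. Of 22 phagocytic receptor genes, 17 were at least 4-fold higher and 0 lower (median 8.33), among them Tyrobp, a signalling adaptor of myeloid receptors, at 713 CPM in MCC and 3426-fold (1805 to 7494) higher. Axl, a receptor for apoptotic cells, was 3.21-fold (3.15 to 3.28) lower in MCC. Of 21 complement and coagulation genes, 13 were at least 4-fold higher and 2 lower (median 4.47). On the lower side Plaur, the urokinase receptor gene, picked out after its values were seen, was 6.97-fold (6.14 to 7.93) lower. Of 32 interferon response genes, 30 were at least 4-fold higher and 0 lower (median 5.01), among them Ifi27l2a at 1213 CPM in MCC and 1748-fold (1224 to 2591) higher, and Bst2 (tetherin) at 15.9-fold (15 to 16.8) higher. Of 28 inflammatory cytokine genes, 10 were at least 4-fold higher and 1 lower (median 2.76). The acute-phase gene Saa3 was 3736-fold (1813 to 9294) higher and the chemokine gene Ccl8 204-fold (167 to 251) higher, whereas Ptgs2, the inducible cyclooxygenase, was 90.1-fold (72.5 to 113) lower. The medians of all 5 lists lay at the 100th percentile of matched random lists.

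Transcription factors of the myeloid lineage differed by gene. Of 23 such genes, 11 were at least 4-fold higher in MCC than in MEF, 1 was lower and 11 were neither (median log2 ratio 1.26, 100th percentile). Spi1, which encodes PU.1, the main myeloid transcription factor, had 261 CPM in MCC and 0.116 CPM in MEF, 2261-fold (969 to 6964) higher. Maf, a factor of mature macrophages, was 14.9-fold (13.8 to 16.1) higher. Egr1 was close in both, at 179.6 and 111 CPM, and Bhlhe40 was 5.56-fold (5.14 to 6.02) lower. Of 23 genes used in reprogramming or blood specification, 10 were at least 4-fold higher and 0 lower. Cebpa stood at 154 CPM in MCC and 17.1 CPM in MEF, Cebpb at 144 and 87.7 CPM, Irf8 at 69.7 and 0.0694 CPM, and Runx1 at 43.4 and 91.5 CPM. Klf4 and Myc were at 125 and 214 CPM in MCC and at 70.9 and 77.1 CPM in MEF. Of 25 pluripotency genes 1 was at least 4-fold higher in MCC, the pluripotency transcription factor gene Sox2, at 15.1 CPM against 0.439 CPM in MEF, 34.4-fold (21.9 to 57.5) higher. Counts per gene symbol would not separate an introduced copy of Spi1, Cebpa, Sox2 or another factor from the cell's own gene. Whether any factor was introduced is not given in the sources used here. Of 21 blood stem and progenitor genes, 4 were higher and 0 lower. These were Cd34 (10.9-fold, 10.2 to 11.8) and the progenitor transcription factor genes Tal1 (at least 239-fold), Lmo2 (332-fold, 180.2 to 693) and Lyl1 (362-fold, 212 to 681), of which Lyl1 was picked out after its values were seen.

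Fibroblast and matrix genes remained at high levels in MCC. Of 37 measured, 31 differed by less than the 4-fold rule, 4 were higher and 2 lower, with a median log2 ratio of −0.63, at percentile 0.03 of matched random lists. The collagen genes Col1a1 and Col1a2 stood at 6563 and 5548 CPM in MCC, 1.36-fold (1.35 to 1.37) and 1.15-fold (1.14 to 1.16) lower than in MEF. Col3a1, another fibrillar collagen gene, was 6.63-fold (6.58 to 6.68) higher. The other genes past the rule were picked out after their values were seen. Higher were the proteoglycan genes Dcn (decorin) at 15.2-fold (14.8 to 15.6) and Lum (lumican) at 28.8-fold (26.9 to 30.9), and the growth factor receptor gene Pdgfra at 6.20-fold (6.01 to 6.39). Lower were Pdgfrb at 4.80-fold (4.64 to 4.96) and Cthrc1, a gene of collagen-producing cells, at 6.67-fold (6.10 to 7.29). Contractile genes were lower as a group: 13 of 16 were at least 4-fold lower and 0 higher, with a median of −3.80. Acta2 (smooth muscle actin) was 31.5-fold (30.7 to 32.2) lower at 162 against 5086 CPM, and the actin-binding genes Tpm1 and Cald1 were 4.30-fold (4.24 to 4.36) and 4.63-fold (4.55 to 4.71) lower. Among genes with the largest counting bounds on the lower side, Ccn2, which encodes connective tissue growth factor, was 114-fold (98.7 to 133) lower and the calponin gene Cnn1 95.7-fold (78.0 to 119) lower. The muscle genes Acta1 and Tnnt2 were 156-fold (97.3 to 268) and 318-fold (108 to 1543) lower, the latter with 3 reads in MCC. Megf10, an engulfment receptor, was 315-fold (144 to 858) lower, Cck (cholecystokinin) 132-fold (87.2 to 211) lower and the Notch target gene Heyl at least 175-fold lower. The connexin gene Gjb2 had 1 read in MCC and was 432-fold (77.1 to 17086) lower. Of 20 genes of the mesenchymal programme 3 were lower and 1 was higher (median −0.92), with Itgb1 (an integrin) at 3.18-fold (3.13 to 3.23) lower and Tgfbr2 (a TGF-beta receptor) at 4.19-fold (4.07 to 4.32) higher. Of the bases of the Ccn2 exons, 23.2% lie in exons of a gene on the opposite strand, so its count is uncertain.

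Few genes of other blood cell types passed the rule in MCC. In MCC 3 of 23 neutrophil granule, 7 of 18 dendritic cell and MHC class II, 4 of 16 megakaryocyte and platelet, 2 of 17 B cell, 2 of 24 T and NK cell and 2 of 20 erythroid genes reached 5 CPM. The median log2 ratio to MEF was 1.59 for the neutrophil granule list (percentile 99.98). It was 1.08 for the dendritic cell and MHC class II list (percentile 99.5) and 0.74 for the megakaryocyte and platelet list (percentile 99.8). The list medians, in the same order, were 0.231, 0.636 and 0.359 CPM in MCC and 0, 0.173 and 0.0347 CPM in MEF. All lay below 1 CPM, so these percentiles describe differences between trace levels. Of 23 neutrophil granule genes 2 were at least 4-fold higher in MCC than in MEF. They were Csf3r, the receptor for granulocyte colony-stimulating factor, at 10.7 CPM, and Lcn2 (lipocalin), picked out after its values were seen, at 7.98 CPM; both had 0 reads in MEF. Of 18 dendritic cell and MHC class II genes 3 were higher: Cd74, the invariant chain, at 35.8 CPM, H2-DMb1 at 16.4 CPM and, picked out after its values were seen, the costimulatory gene Cd86 at 15.3 CPM. Of 17 B cell genes 1 was higher, the lectin gene Cd22 at 6.87 CPM, and of 24 T and NK cell genes 2 were, the costimulatory receptor gene Cd28 at 24.3 CPM and the chemokine gene Ccl5 at 11.9 CPM. Of 20 erythroid genes 1 was higher, the erythropoietin receptor gene Epor at 6.30 CPM. Of 16 megakaryocyte and platelet genes 1 was higher, the chemokine gene Pf4, at 248 CPM and 5361-fold (1484 to 44272) higher. Over all genes, 11720 reached 5 CPM in MCC or MEF; 943 of them were at least 4-fold higher in MCC, 318 at least 4-fold lower, and 89.2% were neither.

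Bone marrow served as a native source of myeloid cells against which the MCC library was set. The BM library also held neutrophil, lymphoid and erythroid transcripts, so a ratio to it does not compare macrophages with macrophages. Macrophage genes went both ways against marrow, most neutrophil, lymphoid and erythroid genes were lower in MCC, and most fibroblast genes were higher. Of 42 macrophage and monocyte genes, 15 were at least 4-fold higher in MCC than in BM, 9 lower and 18 neither. Their median log2 ratio was 1.18, at the 100th percentile of matched random lists. C1qb and C1qc were 36.9-fold (35.5 to 38.4) and 26.4-fold (25.4 to 27.5) higher, and Spp1 318-fold (295 to 342) higher. Lyz2 was close, at 5597 CPM in MCC and 6849 CPM in BM. Cybb, the catalytic subunit of the phagocyte oxidase, was 16.8-fold (16.2 to 17.5) lower. Ptprc, outside the rule for named genes here too, was at 64.3 CPM against 525 CPM, and of 20 pan-leukocyte genes 12 were at least 4-fold lower and 0 higher (median −2.15), with Coro1a (coronin) 6.78-fold (6.66 to 6.90) lower. Spi1 was 1.53-fold (1.5 to 1.57) lower and Maf 17.2-fold (15.8 to 18.8) higher in MCC, in a myeloid transcription factor list with 3 genes higher and 3 lower of 23. Of 21 complement and coagulation genes 11 were higher and 3 lower (median 2.36); C3 was 5.44-fold (5.33 to 5.56) lower. Lysosomal genes had a median of 1.07, with 5 of 27 at least 4-fold higher and 0 lower, led by the cathepsin gene Ctsb at 7.80-fold (7.71 to 7.90) higher.

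The genes lowest in MCC relative to marrow were those of neutrophil granules, 22 of 23 at least 4-fold lower (median log2 ratio −12.21). Ltf (lactoferrin) stood at 0.440 CPM in MCC against 8927 CPM in BM, 20299.9-fold (12999 to 33717) lower. Ngp, S100a9, Camp, Chil3, Mpo, S100a8 and Cd177 encode granule or cytosolic proteins of neutrophils and their precursors. They lay from 8019-fold (6303 to 10369) lower for S100a8 to 19585-fold (10649 to 40841) lower for Camp. In MCC these genes and Ltf had between 6 (Cd177) and 66 (S100a8) reads. Carry-over from BM into MCC was not tested, so their MCC levels are not settled by the folds. B cell genes were lower for 16 of 17 (median −9.09), T and NK cell genes for 14 of 24 with 1 higher (Cd28, 6.07-fold, 5.14 to 7.21), erythroid genes for 19 of 20 (median −10.17) and dendritic and MHC class II genes for 11 of 18 (median −6.16), with H2-Aa 537-fold (335 to 923) lower. Cell cycle genes were at least 4-fold lower for 18 of 34 (median −2.06), with the proliferation marker gene Mki67 13.6-fold (13.1 to 14.1) lower. On the higher side stood fibroblast and matrix genes, 34 of 37 (median 7.25), with Col3a1 3187-fold (2716 to 3765) higher. The leading genes by counting bound were Crabp1 (a retinoic acid binding protein, at least 8334-fold), the imprinted RNA genes H19 (10344-fold, 6461 to 17758) and Rian (5853-fold, 2003 to 28386), Ptn (pleiotrophin, 10366-fold, 5460.3 to 22669.7), Dlk1 (an imprinted Notch pathway ligand, 5131-fold, 2937 to 9930.3), Postn (periostin, 3831-fold, 2393 to 6577) and Fcrls (6945-fold, 2712 to 25492). In total 1943 of 12427 genes at 5 CPM were at least 4-fold higher in MCC and 1678 lower. Scaling by the total count alone moved the median ratio by −0.14 log2 units and turned the split to 1777 higher and 1819 lower, so which side held more genes is not settled.

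**Figure D2:**
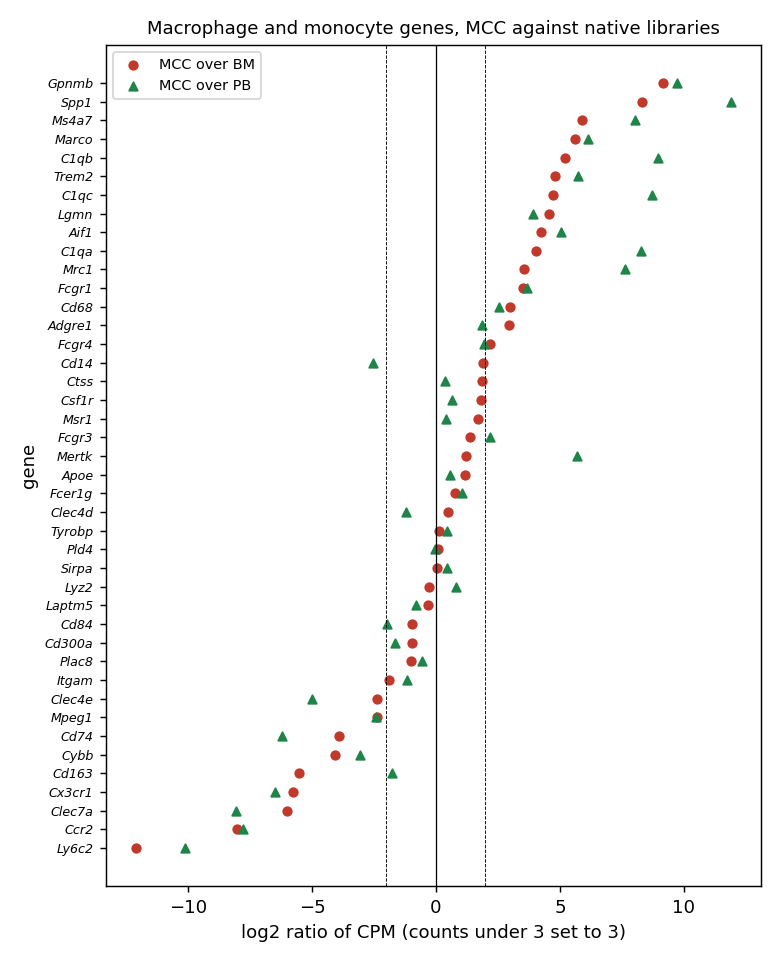
Each row is a macrophage or monocyte gene, with the log2 ratio of its CPM in MCC over BM (red circles) and over PB (green triangles) on the x axis, 1 library each; counts under 3 were set to 3, and the dashed lines mark a 4-fold difference. In each comparison 15 of the 42 genes passed 4-fold on the right, C1qb and Mrc1 among them, and 9 on the left, Ly6c2, Ccr2, Clec7a and Cx3cr1 among them; the list medians are 1.18 against BM and 0.51 against PB.

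Blood cells were the other native reference, and PB is likewise a mixture of cell types. Macrophage and monocyte genes were divided again, with 15 of 42 at least 4-fold higher in MCC than in PB and 9 lower (median log2 ratio 0.51, 81.4th percentile). Spp1 was 3818-fold (2834 to 5275) higher, C1qb 495-fold (419 to 589.6) higher and Cd74 74.0-fold (70.3 to 77.8) lower. The monocyte genes Ly6c2, Ccr2 and Cx3cr1, chosen after their values were seen, stood at 208, 159 and 49.9 CPM in PB. Fibroblast and matrix genes were higher for 31 of 37 (median 10.88). They gave most of the genes with the largest counting bounds, Col3a1 (8549-fold, 6302 to 11913), Postn (11939-fold, 4663 to 43821), Lum (at least 5406-fold), Col6a3 (at least 4464-fold) and Sparc (5176-fold, 3449 to 8165), next to Sfrp1 (a secreted Wnt modulator, 13244-fold, 5675 to 40789), Ptn (11402-fold, 5238 to 31069) and H19 (6141-fold, 4017 to 9920.1). All 24 T and NK cell genes were at least 4-fold lower in MCC (median −9.73), with Il7r, a cytokine receptor of lymphocytes, 1843-fold (935 to 4270.1) lower. B cell genes were lower for 14 of 17 (median −10.54) and neutrophil granule genes for 17 of 23 (median −7.30). The B cell transcription factor gene Pax5 was 9710.4-fold (2688 to 80190.1) lower and S100a9 2669-fold (2064 to 3515) lower. Other leading genes on the lower side were Alas2 (haem synthesis in red cells, 6166-fold, 4144 to 9624), the lymphocyte GTPase genes Gimap3 (7322-fold, 2505 to 35510.1) and Gimap6 (3856-fold, 1956 to 8932), the inhibitory receptor gene Btla (6521-fold, 2231 to 31624) and the lymphoid factor gene Ikzf3 (11381-fold, 2042 to 449586). In MCC, Gimap3 and Btla had 3 reads each, Pax5 had 2 and Ikzf3 had 1. The ratios to PB of Alas2 and 4 haemoglobin genes, traces in MCC, lay within 1.45 times of each other, and the folds of Pax5, Gimap3, Btla and Ikzf3 were at or above that of Alas2, so the MCC level of these genes is not settled by the folds. The PB counts held 9.04% haemoglobin, beside which the erythroid list was lower in MCC for 10 of 20 genes and higher for 1, Epor (17.1-fold, 9.40 to 34.7).

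Inflammatory and cell cycle genes were compared with blood as well. Of 28 inflammatory cytokine genes 7 were higher and 10 lower in MCC than in PB (median log2 ratio −0.84). Ccl8 was 4646-fold (1589.7 to 22533) higher. Il1b was 829-fold (700.3 to 990.2) lower and Cxcl2, a neutrophil chemokine, 2950.0-fold (1816 to 5162) lower. Against BM the same list went the other way, with 10 genes at least 4-fold higher in MCC and 6 lower (median 1.22). The list was higher in PB than in BM by a median of 2.36 log2 units. Pattern recognition genes were lower for 9 of 24 and higher for 2 (median −1.49), with the lectin gene Clec4e 31.8-fold (29.5 to 34.3) lower. Of 32 interferon response genes 26 differed by less than the rule, 2 were higher and 4 lower. Cell cycle genes were at least 4-fold higher for 17 of 34 (median 2.11), and Pcna, a replication factor, was at 134 CPM in MCC and 111 CPM in PB. In total 2699 of 12545 genes at 5 CPM were at least 4-fold higher in MCC and 1927 lower. With DESeq2 size factors the median ratio moved by −0.28 log2 units, by −0.13 with total counts, and the split became 2264 higher and 2328 lower with the former, so the side with more genes is not settled here either.

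The iPSC library is a pluripotent state in the same design. Nearly all pluripotency and epithelial genes were lower in MCC than in iPSC, and most macrophage and fibroblast genes were higher. Of 25 pluripotency genes 24 were at least 4-fold lower in MCC (median log2 ratio −8.77). Dppa5a, Tdgf1 and Esrrb, genes of naive pluripotency and its signalling, had 0 reads in MCC and were at least 18872-fold, at least 7119-fold and at least 2591-fold lower, and Tdh, a threonine dehydrogenase of stem cells, was at least 2609.6-fold lower. Sox2 was 9.79-fold (9.04 to 10.6) lower and the remaining gene, Klf2, was at 51.8 CPM in MCC and 57.6 CPM in iPSC. Of 17 epithelial genes 16 were lower (median −9.23), among them the keratin genes Krt8 (at least 18240.3-fold), Krt18 (46018-fold, 8259 to 1817628) and Krt6a (at least 3640.4-fold), of which Krt6a is not on that list, and the tight junction gene Cldn4 (13607-fold, 2442 to 537475). Macrophage and monocyte genes were higher in MCC for 36 of 42 (median 8.38), with Lyz2 29256-fold (15908 to 61010.2) and Tyrobp at least 12423-fold higher. C1qb, C1qc and Adgre1 had 0 reads in iPSC and were at least 39867-fold, at least 28131-fold and at least 6972-fold higher, and C1qa had 1 read. Wfdc17, a gene of activated macrophages, was at least 8151-fold higher and the angiotensin receptor gene Agtr2 at least 7203-fold higher. Fibroblast and matrix genes were higher for 24 of 37 and lower for 0 (median 3.47), with Col3a1 70.7-fold (69.2 to 72.2) higher and Thbs1 (thrombospondin) 1.84-fold (1.82 to 1.85) lower. Cell cycle genes were lower for 14 of 34 (median −1.89). In total 1410 of 12442 genes at 5 CPM were at least 4-fold higher in MCC and 1215 lower. Total count scaling moved the median ratio by −0.39 log2 units and turned the split to 1161 higher and 1613 lower, from 53.7% to 41.9% of the genes past the rule being higher.

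**Figure D3:**
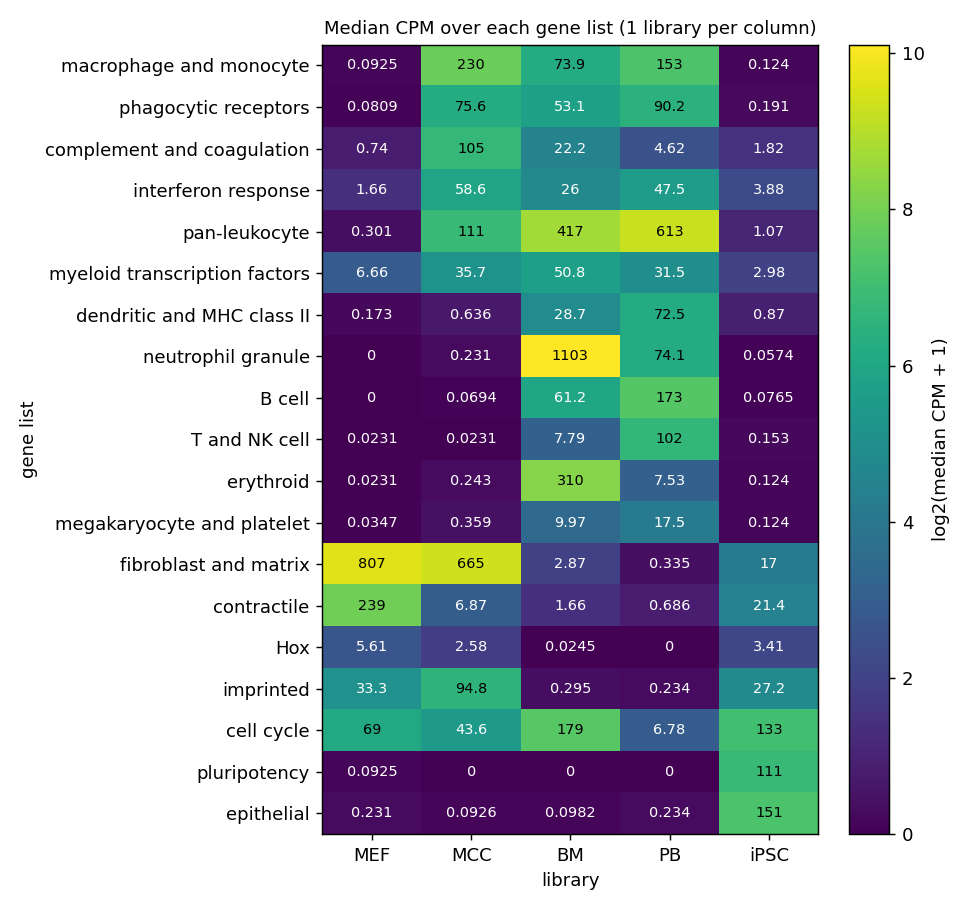
Median CPM over the measured genes of 19 lists (rows) in the 5 libraries (columns, 1 library each), with the colour giving log2(median CPM + 1) and the number the median CPM. The MCC column joins a macrophage and monocyte median of 229.7 CPM to a fibroblast and matrix median of 665 CPM, and its neutrophil, lymphoid and erythroid medians lie below 1 CPM.

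Across 18416 genes at 1 CPM or more in any library, the MCC profile was closest to that of MEF. Its Spearman correlation was 0.902 with MEF, 0.786 with iPSC, 0.725 with BM and 0.651 with PB, against 0.891 between PB and BM and 0.866 between MEF and iPSC. These are correlations across genes, which are not independent replicates. Over the 2000 genes with the largest variance among the libraries the values were 0.660 with MEF and 0.292 with iPSC. There the sign turned with BM (−0.0689) and PB (−0.124). These genes were chosen by variance in the same libraries, so the sign cannot be read apart from that choice.

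The position of MCC between fibroblasts and marrow was read on the genes that part them. Of 1512 genes at least 8-fold higher in BM than in MEF, 470 (31.1%) were also at least 4-fold higher in MCC than in MEF, and 385 lay within 4-fold of the BM level or beyond it. The median gene of that set covered 28.4% of the log2 distance from MEF to BM. Of 1370 genes at least 8-fold higher in MEF than in BM, 212 (15.5%) were at least 4-fold lower in MCC than in MEF, and the median gene covered 10.7% of the distance. Lists drawn independently would share 111 and 34.0 genes. In 100 simulated libraries drawn from MEF with counting error only, 0 genes passed in either direction. At 5 CPM and this depth, counting error does not move a gene 4-fold, so that outcome was fixed in advance. The simulated value leaves out real effects and the independent value the shared MEF library, which cannot be divided, so part of the excess may come from that shared control. With PB in place of BM, 491 of 1749 genes (28.1%) and 212 of 1740 (12.2%) passed.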

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

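No paired analysis was possible because each group had 1 library, and no library could be left out of a group for the same reason. TMM factors without PB (949 genes higher and 312 lower in MCC than in MEF) and a PB carry-over subtraction (942 higher) were chosen after seeing the data, as was the rescaling of single genes and of most list medians. Without a filter on the level, more genes were admitted by construction: 1851 were higher and 885 lower in MCC against MEF, 3368 and 3666 against BM, 4219 and 4869 against PB, and 2451 and 3242 against iPSC. With a minimum of 20 CPM, fewer genes were admitted: 589 were higher and 162 lower against MEF, 1243 were higher against BM, 1798 were higher against PB, and 613 were lower against iPSC. Every other count of genes at 4-fold stayed within 1.5 times the reported one. Of the list medians 65 reached 4-fold and kept their sign under the scalings tried, while 15 smaller ones, up to 0.36 log2 units, changed sign. The genes named by their counting bound were also rescaled, and all 128 values kept their direction and stayed past 4-fold. The largest shift of a list median by scaling was 0.39 log2 units. These outcomes were therefore fixed in advance for the 65 medians and for genes chosen for their extreme folds.

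Pearson correlations were 0.904 with MEF, 0.730 with BM, 0.661 with PB and 0.794 with iPSC. Over genes at 5 CPM the Spearman values were 0.859, 0.613, 0.536 and 0.704. Over the 2000 most variable genes they were 0.660, −0.0689, −0.124 and 0.292, so those with BM and PB changed sign. Those genes were chosen by variance in the same libraries, and the effect of that choice was not tested. The mean of the macrophage and monocyte genes against MEF was 8.48 log2 units. The fibroblast and matrix genes gave −0.67 with total counts and −0.31 as a mean; the mean weighs the few genes far higher in MCC. With 16-fold in place of 8-fold between BM and MEF, 33.5% of the genes high in BM and 17.9% of those high in MEF passed. With PB in place of BM, at 8-fold, 28.1% and 12.2% passed. The cause of these shifts was not tested. Depth limits values near the floor of 3 counts, where ratios are bounds or have wide intervals.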

Other observations

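All tests of explanations in this part were chosen after the results were seen. Most lysosomal, lipid efflux and cholesterol synthesis genes did not pass the 4-fold rule between MCC and MEF. Of 27 lysosomal genes 4 were at least 4-fold higher in MCC and 0 lower (median log2 ratio 1.17). The cathepsin gene Ctsb was 7.52-fold (7.43 to 7.60) higher, and Ctss, a cathepsin of antigen-presenting cells picked out after its values were seen, was 5618-fold (2407 to 17303) higher. Of 14 lipid efflux genes 6 were higher and 0 lower (median 1.80), with the fatty acid carrier gene Fabp5 4.69-fold (4.61 to 4.78) higher and the desaturase gene Scd2 2.33-fold (2.30 to 2.36) lower. None of 18 cholesterol synthesis genes passed 4-fold, and their median was −1.21, with Cyp51, a sterol demethylase, 3.11-fold (3.01 to 3.21) lower. Of 14 genes of alternative macrophage activation 5 were higher and 0 lower (median 3.31), with the interleukin receptor gene Il4ra 6.88-fold (6.68 to 7.08) higher. Of 10 adipocyte genes 3 were higher and 0 lower, with the lipoprotein lipase gene Lpl 9.16-fold (8.80 to 9.54) higher. Of 8 osteoclast genes 2 were higher and 0 lower, and Ctsk, the osteoclast cathepsin, was at 102 CPM in MCC and 136 CPM in MEF.

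Most imprinted, Hox and cell cycle genes lay within 4-fold of MEF or below the minimum level. Of 17 imprinted genes 3 were at least 4-fold higher in MCC than in MEF and 0 lower (median log2 ratio 0.95), with Dlk1 45.3-fold (43.0 to 47.8) higher and H19 3.14-fold (3.11 to 3.17) higher. Of 30 embryonic Hox genes 1 was lower and 0 higher (median −1.35). That gene was Hoxd13, picked out after its values were seen, at 0.0694 CPM in MCC and 15.1 CPM in MEF, a gene of the distal limb. Hoxa10 was at 20.9 and 35.5 CPM and Hoxb9 at 15.5 and 54.8 CPM. None of 34 cell cycle genes passed 4-fold (median −0.79), with Mki67 2.32-fold (2.22 to 2.42) lower. Of 9 muscle genes 2 were lower, and of 10 neural genes 3 were lower and 1 higher, with Ncam1, an adhesion gene, 7.72-fold (7.24 to 8.23) lower. Between the native libraries, inflammatory cytokine genes were higher in PB than in BM by a median of 2.36 log2 units, and T and NK cell genes by 3.29. Il1b stood at 2573 CPM in PB and 129 CPM in BM and the immediate-early gene Nr4a1, picked out after its values were seen, at 1978 and 35.1 CPM.

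Macrophage and fibroblast genes were both high in the MCC library. Added marrow or blood cells with the profile of the BM or PB library are argued against. The median neutrophil gene in MCC lay at 0.635% of its PB level and 0.0210% of its BM level. The median macrophage gene lay at 142% and 227% of those levels. Marrow or blood cells with another profile, such as macrophages without neutrophils, were not tested. Unchanged fibroblasts with the profile of the MEF library are argued against as well, if diluted by cells that lack these transcripts. Of 37 fibroblast genes, 12 lay over 2-fold from the list's median ratio to MEF. The spread between fibroblast cultures was not measured. Dilution by cells that express some of these genes, and fibroblasts of another preparation, were not tested. From which fibroblasts the MCC cells came is not given in the sources used here. Macrophages already present among the fibroblasts cannot be told apart from converted cells, since Adgre1 in MEF was limited to 0.0173% of its MCC level but the libraries do not record whether such cells could have multiplied. A hypothesis left open and untested is that converted cells may hold both programmes. They may also sit beside altered fibroblasts or fibroblasts of another preparation, which bulk libraries do not separate.

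Haemoglobin reads appeared at a trace level in the MCC library, 474 reads against 0 in MEF and 4 in iPSC. Carry-over from the blood sample or library is a candidate explanation: the ratios to PB of 4 haemoglobin genes and Alas2 differed by at most 1.45 times, although Alas2 also had 9 reads in MEF and 9 in iPSC. Red cells with the profile of the PB library would give the same ratios, so these do not tell such cells from carry-over. Erythroid cells with a marrow profile are argued against, since 10 other erythroid genes had a median of 17.6% of the reads such cells would bring. Misassignment of PB reads at 1 rate to every library is argued against, since the upper bound in MEF and iPSC was 1.80% of the MCC level. Carry-over from PB does not account for 7 of 33 lymphoid genes, each over 10 times its level. These were Cd28 (1050 reads), Ccl5 (515), Cd22 (297), Ighm (162), Cd4 (141), Vpreb1 (20) and Bank1 (18). The other lymphoid genes had 44 reads where 20.5 would be brought. Nor does it account for 1216 reads of neutrophil genes, where 46.3 would be brought. That sum was not divided by gene, and it does not show an excess across the list. Csf3r and Lcn2 were above 5 CPM in MCC. Ltf, Ngp, S100a9, Camp, Chil3, Mpo, S100a8 and Cd177 had between 6 (Cd177) and 66 (S100a8) reads. In MCC 3 of 23 neutrophil granule genes reached 5 CPM, and the list median was 0.231 CPM. Carry-over from BM was not tested, nor were erythroid cells with another profile.

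Fibroblast genes were also present in the iPSC library, at a median of 5.58% of their MEF level. Feeder cells with the profile of the MEF library are argued against, since 20 of 37 members lay over 4-fold from that median share, with Thbs1 at 80.6% and Postn at 0.0322%, both picked out after their values were seen. Feeder cells with another profile, and expression by the pluripotent cells themselves, remain open and were not tested.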
